A study of Mus musculus with 6 samples.

How the data were processed

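Cortex RNA was sequenced from 3 wild-type and 3 Tle4-/- mutant samples at postnatal day 0, and the authors deposited 1 table of genes for the whole series. Per the labels' protocols, the cortex was dissected in cold buffered salt solution and flash frozen, and total RNA was extracted with spin columns and treated with DNase. The submitters' processing notes name HISAT2 2.0.4, StringTie and edgeR, and the builds GRCm38.p4 and mm10. Read trimming, the program that made the counts, the annotation release and whether counting used the strand are not given in the sources used here.

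Per the file headers, the table deposited by the authors holds a whole-number count per gene and library, the FPKM of each gene in each library, the authors' mean FPKM of each genotype, and the p-value and adjusted p-value of the authors' own comparison. The deposited counts were used as they stand, and their totals differed between libraries, from 18617408 to 21632607. The deposited FPKM values and the authors' p-values served only to describe the authors' comparison. The authors' fold change column was not used, because it holds cells that are not numbers. In 25 rows a spreadsheet had turned the gene symbol into a date, and the symbol was restored from the gene ID. Of the 23621 gene IDs, 23456 are in the GENCODE M21 annotation of GRCm38, each on the chromosome the table gives, and 20292 start within 1 base of it. Coordinates are those of the deposited table, on GRCm38.

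Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the genotypes, libraries were scaled with TMM factors, and genotypes were compared with a robust quasi-likelihood fit and a 2-sided test, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change is the mutant over the wild type. Its standard error (SE) is the absolute log2 fold change over the square root of the test's F value. Levels are TMM-normalized CPM, given as mean ± SD over 3 libraries. The same steps were tested on simulated data: counts for 16078 genes were drawn from the means and depths of these libraries with 200 genes changed. The test called 172 genes, of which 8 were false, and recovered 65.6% of the genes changed 2-fold and 96.3% of those changed 4-fold. Changed genes were taken only from genes above a minimum mean count. Genes were drawn independently, with a spread set by their level alone, so these rates may be too favourable for the real libraries.

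Before the data were examined, 28 gene lists were fixed: neuron classes of the cortex, progenitors, glia, signalling targets, and markers of blood, vessels, meninges, choroid plexus and neighbouring brain regions that a cortex dissection can hold. The 27 lists with at least 3 tested members were compared with all other genes by camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation. Each list was also tested by fry against no change, without reference to other genes. Both used log2 CPM with a prior count of 2. Tle4 was in no list. Members were also counted with p-values adjusted over the list alone. A list score per library is the mean log2 CPM of the members after subtracting each member's mean over the 6 libraries. Scores were compared by an exact 2-sided permutation test, which cannot give a p below 0.1 with 3 libraries against 3. Genes starting within 10 Mb of Tle4 were compared with all others by Fisher's exact test, at the adjusted threshold as planned and then at an unadjusted p under 0.05.

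The genes named in the text follow a rule fixed at the same time. It takes Tle4, and Fezf2, Bcl11b, Tbr1, Foxp2, Zfpm2, Rorb, Tle1, Tle2 and Tle3 whatever their result. Of genes past the threshold with a mean of at least 1 CPM and no overlap between the genotypes, it takes the 10 higher and the 10 lower with the largest change, without unnamed loci, pseudogenes and the sex-linked check genes. From each list it takes up to 4 members with the smallest p. Some results the rule takes are not reported here. Any other gene named was chosen after its values were seen.

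The alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, limma-voom, no filter beyond 1 count, a filter at a mean of 1 CPM, a replicate block, each library left out, no X or Y genes, a further 2-fold threshold, and windows of 5 and 20 Mb. A fit with sex as a covariate was planned only if both sexes were in both genotypes, which was not so. Further alternatives were chosen after seeing the data: removing 48 rows (mitochondrial genes, their chromosome 1 copies and rows on in some libraries and off in others), and a meninges score as a covariate. A row counted as on and off when it reached 5 CPM in a library and was at least 30 times lower in another, leaving out members of the fixed lists, Y-linked genes and rows whose correlation with the meninges score was above 0.9. Its levels and ratios were also varied, with and without the rule on the meninges score. The gene groups of the tests on striatal tissue and X-linked genes were picked with their values in view, and both tests were repeated with genes first left out. Chromosome 1 copies were paired with mitochondrial genes by shared words of 25 bases in the GENCODE M21 transcripts.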

Results

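Cortex RNA from newborn mice carrying a Tle4-/- null mutation was compared with that of wild-type littermates, with 3 libraries per genotype and postnatal day 0 as the only age. Tle4 encodes a Groucho-family co-repressor of transcription found in deep-layer cortical neurons, and the series addresses how identities of projection neurons are set in the developing cortex. The libraries held 18617408 to 21632607 counts over 23621 genes. All animals were of a mixed strain background, and the labels do not tie libraries to litters, so p-values set the genotype difference against the spread between these samples. Sex could not be separated from genotype in these libraries, so the p-values do not isolate an effect of genotype.

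Tle4 fell in the mutant to 0.480 of the wild-type level (log2 fold change -1.06, SE 0.14, edgeR adjusted p = 0.0377). The gene (ENSMUSG00000024642) lies on chromosome 19 from 14448072 to 14598051. It stood at 169 ± 27.8 CPM in the wild type and 81.0 ± 10.1 CPM in the mutant (SD, n = 3 each), and every mutant library was below every wild-type library. The table gives 1 value per gene, so which part of Tle4 the remaining counts come from was not analysed here. The direction held whichever library was left out, with log2 fold changes from -1.17 to -0.93. The edgeR adjusted p passed the threshold only without wild-type replicate 2 (0.0306), and was 0.0784 without wild-type replicate 1, 0.162 without wild-type replicate 3, and 0.10, 0.111 and 0.135 without mutant replicates 1, 2 and 3.

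Fezf2, the transcription factor that specifies subcerebral projection neurons, rose 2.47-fold in the mutant (log2 fold change 1.31, SE 0.14, edgeR adjusted p = 0.0117). Its level went from 65.7 ± 10.8 to 162 ± 19.5 CPM (SD, n = 3 each), on chromosome 14 from 12341892 to 12345865. Ctgf, a secreted matrix-associated protein that marks the subplate, fell to 0.312 of the wild type, from 23.1 ± 0.356 to 7.20 ± 1.79 CPM (log2 fold change -1.68, edgeR adjusted p = 0.0145). Nptx1, a neuronal pentraxin, fell to 0.458 of the wild type. In total 18 of 16274 genes tested differed between the genotypes by edgeR, 8 higher and 10 lower in the mutant. Of these, 3 were mitochondrial genes and 1 was Xist, and the other 14 were autosomal protein-coding genes. At an unadjusted p under 0.05 there were 561 genes, against 814 by chance, and 7.93% of genes had genotypes that did not overlap, against 10% by chance for 3 libraries against 3.

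Zfp422, a zinc-finger gene, rose 3.31-fold, from 27.1 ± 5.85 to 89.4 ± 3.53 CPM (log2 fold change 1.72, SE 0.16). Adamts14, a procollagen-processing protease, rose 2.97-fold (log2 fold change 1.57) from 3.03 CPM in the wild type, and Tcerg1l rose 1.84-fold, from 33.9 to 62.4 CPM. Sh3gl2, the endocytic protein endophilin of presynaptic terminals, fell to 0.362 of the wild type, from 152 ± 8.02 to 55.0 ± 4.02 CPM (log2 fold change -1.46, SE 0.10, edgeR adjusted p = 0.000483). Rab40c, a small GTPase, fell to 0.408 of the wild type, and Ap3m1, a subunit of an endosomal adaptor complex, to 0.547. Cabp7, a calcium-binding protein, fell from 5.99 to 1.54 CPM. Ube2l3, a ubiquitin-conjugating enzyme, fell from 62.5 ± 28.8 to 4.33 ± 0.221 CPM. Gal3st4 had 0 or 1 counts in each wild-type library and 13 to 36 in the mutants, below the level set for named genes, and its overlapping neighbour Gm43720 had 21 to 110 counts in the wild type and 0 in every mutant. Ctgf, Sh3gl2, Rab40c, Ap3m1, Cabp7, Ube2l3 and Gal3st4 overlap other genes in the table, so reads could be divided between neighbours.

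Leaving out 1 library at a time, Zfp422 and Sh3gl2 passed the threshold in all 6 fits, as did Xist and the mitochondrial genes mt-Co1, mt-Co2 and mt-Nd4. Fezf2 missed it only without mutant replicate 3 (edgeR adjusted p = 0.0628) and Rab40c only there too (0.0532), while Adamts14, Cabp7 and Gal3st4 missed it in all 6. Tle4, Tcerg1l, Nptx1 and Ap3m1 missed it in 5 of the 6, Ctgf in 4, and Ube2l3 in 3. Without mutant replicate 3 the number of genes past the threshold was 8, and by the DESeq2 Wald test on all libraries it was 58, with all 18 genes among them.

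**Figure D1:**
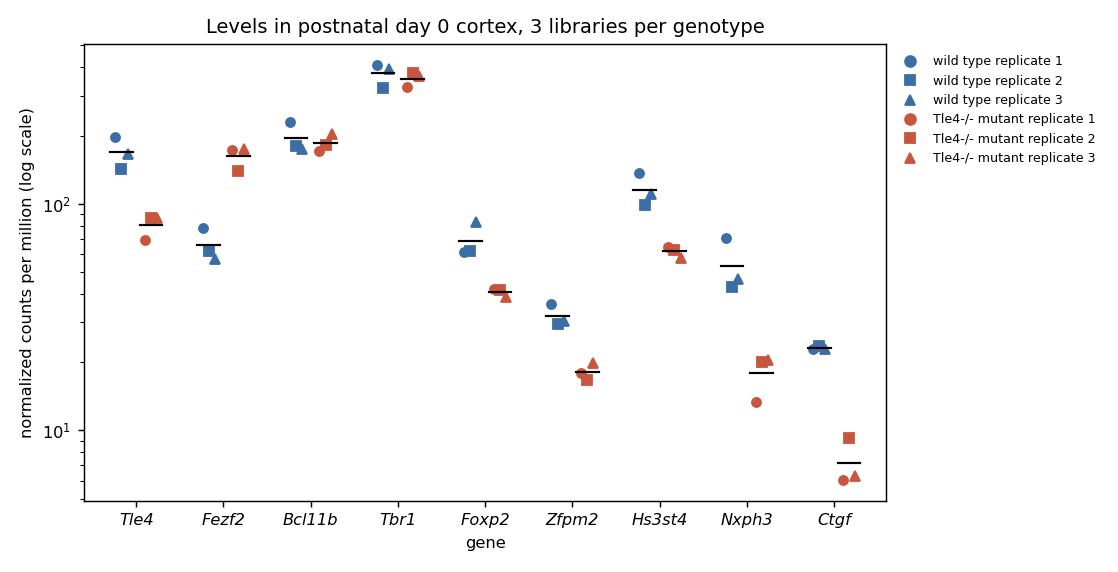
Normalized CPM on a log axis for 9 genes, with 1 point per library (blue wild type, red mutant, marker shape for the replicate) and a black line at the mean of 3. Mutant libraries of Tle4, Foxp2, Zfpm2, Hs3st4, Nxph3 and Ctgf lie below all wild-type libraries, those of Fezf2 lie above, and those of Bcl11b and Tbr1 overlap.

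Markers of corticothalamic neurons, the deep-layer cells that send axons to the thalamus, ranked lower in the mutant as a list by camera (adjusted p = 0.000665), but not with an estimated correlation (p = 0.0201, adjusted p = 0.272), and 8 of 14 lay below 0. None of the 14 passed the threshold over all genes tested, and 5 were lower when adjusted over the list alone. These were Hs3st4, a heparan sulfate sulfotransferase (log2 fold change -0.90, 115 to 61.6 CPM), Nxph3, a neurexin ligand (-1.58, 53.3 to 17.9 CPM), the transcription factors Zfpm2 (-0.82) and Foxp2 (-0.75), and Syt6 (-0.66), named after its value was seen. Their edgeR adjusted p over all genes were 0.0522, 0.0789, 0.121, 0.173 and 0.544. Tbr1, a regulator of corticothalamic identity, had a log2 fold change of -0.08 (SE 0.11), at 376 ± 45.1 CPM in the wild type and 357 ± 25.6 CPM in the mutant (SD, n = 3 each). The list's median log2 fold change was -0.06 and its mean -0.32. The median was -0.02 without wild-type replicate 1, -0.18 and -0.12 without wild-type replicates 2 and 3, -0.11 without mutant replicate 2, and 0.01 with a meninges score as a covariate, added after seeing the data. With that covariate the list's mean was -0.29, and 6 members were lower when adjusted over the list alone. Its adjusted p by camera was then 0.00395, and 0.636 with an estimated correlation. In the same libraries the striatum list was lower, and striatal neurons also use Foxp2.

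Among 17 markers of subcerebral projection neurons, 1 rose over all genes (Fezf2) and 3 were higher when adjusted over the list alone. Beside Fezf2 these were Cntn6, a contactin (log2 fold change 0.79, 34.8 to 60.1 CPM), and Ldb2, a LIM-domain binding cofactor (0.35, 110 to 140 CPM). Neto1, at -0.40, did not pass either threshold. Bcl11b, which acts in the same neurons and downstream of Fezf2, had a log2 fold change of -0.07 (SE 0.13), with 194 ± 31.0 CPM in the wild type and 185 ± 16.1 CPM in the mutant (SD, n = 3 each). The list had a camera adjusted p of 0.102, which was 0.0483 without wild-type replicate 1 and 0.0457 without mutant replicate 3, and 0.0453 by fry's test for change in either direction.

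Of 12 subplate markers, 1 fell over all genes (Ctgf). Adjusted over the list alone, 3 were lower and 2 were higher. Cplx3, a synaptic complexin, and Nxph4 had log2 fold changes of -1.80 and -0.89, and Pappa2 and Abca8a of 0.62 each, Abca8a being named after its value was seen. The list was not called by camera (adjusted p = 0.114), which pointed down, and 7 of 12 members lay below 0. By fry's test for change in either direction the adjusted p was 0.00189. The list score was 0.14, 0.23 and 0.08 in the wild-type libraries and -0.23, -0.02 and -0.20 in the mutants (exact permutation p = 0.1, the smallest possible).

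Callosal, upper-layer and glutamatergic lists held no member past the threshold, over all genes or over the list alone. Rorb, a layer-specific nuclear receptor, had a log2 fold change of 0.11 (SE 0.13). Among callosal markers the smallest p belonged to Plxnd1 (log2 fold change -0.29), and among upper-layer markers to Rasgrf2 (0.37). The upper-layer list had a median of -0.01 and a mean of 0.05, with camera pointing up at adjusted p = 0.505. The other Groucho genes gave log2 fold changes of -0.05 for Tle1, 0.43 for Tle2 and 0.13 for Tle3, none past the threshold.

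Radial glia markers were higher in the mutant as a list by camera (adjusted p = 0.000302, and 0.398 with an estimated correlation), with 11 of 12 above 0 and a median log2 fold change of 0.20 (0.13 without wild-type replicate 3). The call was lost without mutant replicate 2 (adjusted p by camera 0.0856), and no member passed the threshold, over all genes or over the list alone. Ptprz1, a receptor phosphatase of progenitors, gave 0.33 (599 to 753 CPM), and Nes, the intermediate filament nestin, 0.25. The oligodendrocyte lineage list was also higher by camera (adjusted p = 0.0278, and 0.398 with an estimated correlation; median 0.15), with 9 of 9 members above 0, led by Olig1 at 0.31. That call was lost with no filter beyond 1 count (adjusted p by camera 0.0843), and without wild-type replicates 1 and 3 and mutant replicate 1 (0.165, 0.0644 and 0.316 by camera). Axon guidance genes were lower as a list by camera (adjusted p = 0.0352, and 0.398 with an estimated correlation), with 23 of 30 below 0. This call was lost without wild-type replicates 1 and 3 and mutant replicates 1 and 2 (adjusted p by camera 0.136, 0.07, 0.104 and 0.168), and its median of -0.09 was -0.05 without wild-type replicate 3. The netrin gene Ntn1 gave -0.73 and Slit1 -0.45. No member of the oligodendrocyte or axon guidance lists passed the threshold, over all genes or over the list alone. Meningeal markers were nearly absent from wild-type replicate 1, and with a meninges score as a covariate, the adjusted p of these 3 lists by camera were 0.0124, 0.0855 and 0.0855.

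Striatal markers were lower in the mutant by camera (adjusted p = 1.04e-14), but not with an estimated correlation (p = 0.0193, adjusted p = 0.272), and 14 of 15 lay below 0, with a median log2 fold change of -0.64. Adjusted over the list alone, 6 were lower. Ebf1, a transcription factor of striatal projection neurons, gave -1.39 (24.1 to 9.17 CPM), Drd2, a dopamine receptor, -1.24 (4.72 to 1.99 CPM), and Ikzf1 -1.39. The list score was 0.35, 0.10 and 0.65 in the wild-type libraries and -0.23, -0.47 and -0.39 in the mutants (exact permutation p = 0.1, the smallest possible). Interneuron markers were lower as a list too (camera adjusted p = 0.0267, median -0.06, adjusted p = 0.341 with an estimated correlation). The call was lost with the meninges covariate (0.0855) and without wild-type replicates 1 and 3 and mutant replicate 3 (adjusted p by camera 0.135, 0.0597 and 0.0890), and the median was -0.10 without mutant replicate 2. None of its 19 members passed the threshold, over all genes or over the list alone. The distal-less genes Dlx6 (-0.98) and Dlx5 (-0.42), and Sp9 (-0.56) and Slc32a1 (-0.36), had the smallest p.

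Meningeal markers were called higher by camera (adjusted p = 0.00821, and 0.767 with an estimated correlation; median log2 fold change 0.22). The list score was -3.74 in wild-type replicate 1, 1.67 and 0.20 in the other wild types, and 0.24, 1.16 and 0.47 in the mutants. Col1a1 had 28 counts in wild-type replicate 1 and 618 to 2092 in the other libraries. The call was lost without that library (median -0.35, adjusted p by camera 0.160) and without mutant replicate 2 (-0.16, 0.148). It was also lost with the list's own score as a covariate (0.17, 0.0855), but that score is made from these same members, so this loss decides nothing. The median was 1.53, 0.03 and 0.45 without wild-type replicates 2 and 3 and mutant replicate 1. With a replicate block the median was 0.95 (adjusted p by camera 1.23e-05). Ttr, a choroid plexus transcript, had 1789 counts in mutant replicate 3 and 1 to 5 in each other library. In all, 7 of 27 lists were called by camera, 0 with an estimated correlation (3 at an unadjusted p under 0.05), 0 by fry in 1 direction, and 4 by fry in either direction: subplate (0.00189), corticothalamic (0.00680), striatum (0.0144) and subcerebral (0.0453). The other 20 lists, which include the proliferation, intermediate progenitor, astrocyte, microglia, endothelial, erythroid, choroid plexus, thalamus, hippocampus, Wnt, Notch, immediate early and stress lists, had camera adjusted p of 0.102 or more. Without wild-type replicate 2 the Wnt, astrocyte, endothelial and erythroid lists were called too (adjusted p by camera 0.0393, 3.75e-05, 6.50e-06 and 0.00723), as were the endothelial and erythroid lists without mutant replicate 1 (0.0106 and 0.0195). The synaptic and hippocampal lists had a median below 0 while camera pointed up.

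**Figure D2:**
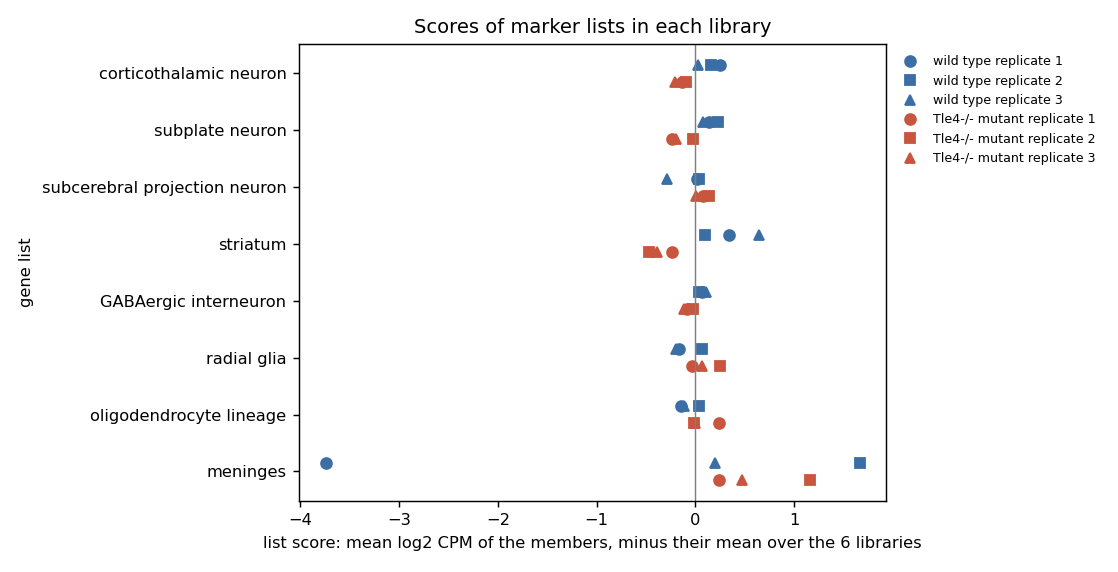
Score of 8 marker lists in each library (x axis, mean log2 CPM of the members relative to their mean over 6 libraries; blue wild type, red mutant). Striatum scores are above 0 in all wild types (0.10 to 0.65) and below 0 in all mutants, and the meninges score of wild-type replicate 1 stands apart at -3.74. Corticothalamic, subplate and interneuron scores are also above 0 in all wild types and below 0 in all mutants.

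Xist, the X-inactivation transcript made in females, had 35, 11 and 37 counts in the wild-type libraries and 72840, 66194 and 79080 in the mutants. The Y-linked gene Ddx3y had 1463 and 1891 counts in wild-type replicates 1 and 2, 2 in wild-type replicate 3, and 0 to 2 in the mutants. Sex therefore could not be separated from genotype in these libraries. Wild-type replicate 3 carried neither signal. Without X and Y genes 15 genes passed the threshold.

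The mitochondrial gene mt-Co1 had 1, 0 and 0 counts in the wild-type libraries and 180109, 168510 and 160285 in the mutants, and mt-Nd4 had 47221, 59621 and 46196 in the wild types and 0, 0 and 1 in the mutants. Both genes encode subunits of the respiratory chain. Some closer neighbours switched too: mt-Co2 had 1, 1 and 0 counts in the wild types and 562, 532 and 266 in the mutants. The gene mt-Nd4l, which overlaps mt-Nd4, had 241, 189 and 95 in the wild types and 0, 0 and 21 in the mutants. In contrast, mt-Nd1, mt-Nd2, mt-Nd5 and mt-Cytb were similar in both genotypes, with a median absolute log2 fold change of 0.01. These were picked because no copy of them is listed on chromosome 1. Other neighbours were near 0 in both genotypes: mt-Atp8, mt-Atp6 and mt-Co3 had 0 to 2 counts in every library. Gm10925, the chromosome 1 copy of mt-Atp6, had 52547 to 63845 counts. The gene mt-Nd3 had 2388 counts in mutant replicate 3 and 0 to 3 in the other libraries. Copies of mitochondrial sequence on chromosome 1 that the table lists also switched in single libraries: Gm28439 had 0 counts in mutant replicate 3 and 19245 to 28509 in the other libraries. Without mitochondrial genes, these copies and other rows that were on in some libraries and off in others, 12 genes passed the threshold, 4 higher and 8 lower in the mutant, all among the 18. Xist was among the 12. Gal3st4, Cabp7 and Tcerg1l lost the call, the latter 2 with edgeR adjusted p of 0.0553 and 0.0508.

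**Figure D3:**
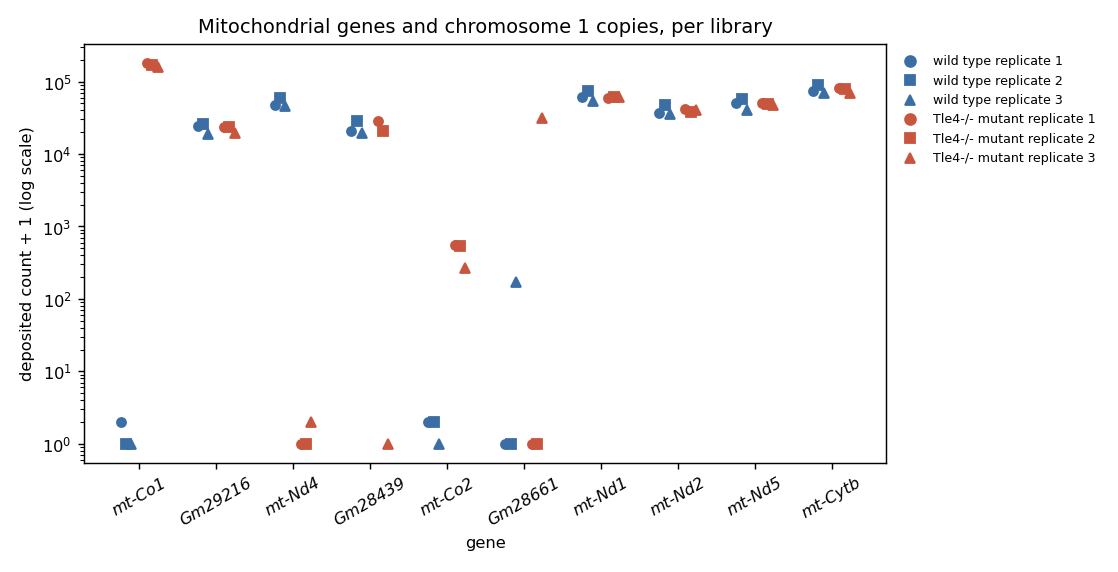
Deposited counts plus 1, on a log axis, of mitochondrial genes and 3 chromosome 1 copies (Gm names), with 1 point per library (blue wild type, red mutant). The gene mt-Co1 is at 0 or 1 counts in the wild types, mt-Nd4 at 0 or 1 in the mutants, and mt-Nd1, mt-Nd2, mt-Nd5 and mt-Cytb are alike in all 6.

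Genes linked to Tle4 on chromosome 19 were examined because littermates of mixed background can differ in strain alleles near a targeted gene. Within 10 Mb of Tle4, 237 genes were tested, 0 passed the threshold by edgeR, DESeq2 or limma-voom. With 17 genes called elsewhere 0.248 would be expected there, so the planned test on called genes could show no difference. At an unadjusted p under 0.05 there were 7, a count added to the plan. That was 2.95% against 3.45% elsewhere (odds ratio 0.852, Fisher's exact test p = 0.857, 95% interval 0.337 to 1.80). Within 5 Mb the odds ratio was 2.13 (7.02% against 3.43%, Fisher's exact test p = 0.132), and within 20 Mb 0.708 (p = 0.439 by the same exact test).

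The authors' deposited table gives an adjusted p under 0.05 to 68 genes, 25 higher and 43 lower in the mutant, and the 18 genes called here were all among them. Of the 68, 55 were tested here. The authors' deposited table also gave adjusted p of 8.88e-05 for Hs3st4, 2.78e-07 for Nxph3, 0.0139 for Foxp2 and 0.0292 for Zfpm2.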

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

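The removal of switching rows and the meninges covariate were chosen after seeing the data. The DESeq2 Wald test gave 58 genes (21 higher, 37 lower) in place of 18, all 18 among them. The fit with a replicate block gave 9 genes (5 higher, 4 lower), all among the 18, and Tle4 at -1.05 with an adjusted p of 0.207 (over all alternatives 5.33e-08 to 0.207). The cause was not tested. Same-numbered libraries had correlations of -0.06, 0.10 and -0.02 after removing genotype means, and only number 2 correlated best with its own number. These few correlations gave no sign that numbers pair the samples but cannot exclude it. Leaving out 1 library gave 8 to 19 genes, 4 to 8 higher and 4 to 12 lower, and the lowest count was without mutant replicate 3. Tle4 then lay between -1.17 and -0.93, and the number of lists called between 4 and 11 (4 without wild-type replicate 1 or mutant replicate 2, 11 without wild-type replicate 2). With fewer libraries the test has less power, and no other cause was tested. Dropping the mitochondrial and switching rows left 4 genes higher, Xist among them. Lists called numbered 3 with the meninges covariate and 0 with an estimated correlation, against 7. The 7 include the meninges list, from whose own members that covariate was made. The meninges list reversed to a median of -0.35 without wild-type replicate 1, the library that nearly lacks its markers, was lost without mutant replicate 2 (-0.16), and reached 1.53 without wild-type replicate 2. Corticothalamic and striatum lists were called in all 13 alternatives that test lists with the preset correlation. Of the 18 genes, the fits without 1 library called 6 to 13. The others called these numbers of them: size factors 18, no filter 18, limma-voom 17, the 1 CPM filter 16, the 2-fold threshold 16, no X or Y genes 15, the meninges covariate 15, and without switching rows 12. No gene near Tle4 was called in windows of 5, 10 or 20 Mb. In named genes, 376 of the values under alternatives stayed on the same side of the threshold, 59 lost the call and 11 gained it. For lists 325 stayed, 17 lost it, 8 gained it and 1 reversed. A reversal was counted only where the main fit or the alternative made a call, for lists by camera's direction. Values that were not called, and list medians such as the corticothalamic one, could therefore change sign and still count as having stayed. The planned change of pseudocount was for normalized values and was not run, the prior count of 2 in the list tests was not varied, and sex could not be a covariate.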

Other observations

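The tests on mitochondrial genes, striatal tissue, the sex of wild-type replicate 3 and chromosome positions were chosen after the results were seen, and their gene groups were picked with the values of those genes in view; the splits, the Tle4 region and the meninges covariate were set before their own results, the covariate after the list scores had been seen.

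Among 15686 autosomal genes, 42 had an edgeR p under 0.001, against 15.7 by chance, and 14 of these were past the threshold. Of the other 28, 20 were lower and 8 higher in the mutant. Named here after their values were seen, the lower ones include the transcription factor gene Dach1 (log2 fold change -0.99), the purinergic receptor P2ry1 (-1.35), Lypd1 (-0.89) and the potassium channel subunit Kcnab1 (-0.88), with edgeR adjusted p from 0.0971 to 0.278. Of the 10 ways to split the 6 libraries into 3 and 3, 1, the real one, gave 18 genes, and the highest other split gave 4; 10 splits cannot give a share under 0.05. The fullest 10 Mb window held 3 of the 42 genes, and the 95th percentile of 10000 shuffles was 4. Near Tle4 the odds ratio for an unadjusted p under 0.05 was 0.852 within 10 Mb (95% interval 0.337 to 1.80) and 2.13 within 5 Mb, so linked strain alleles stay open.

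Counts of mt-Co1 and mt-Nd4 switched between the genotypes. A shift of all reads to the paired chromosome 1 copy would keep the sum of gene and copy level, but the sums differed by at least 2.20 on the log2 scale. The missing reads were therefore not counted on the paired copy. Each copy is shorter than its gene, so the sums cannot tell where those reads went. In mutant replicate 3 the sum of mt-Nd4 and its copy was 0.0516 CPM, against 1322 and 1077 in mutant replicates 1 and 2. A change in mitochondrial transcription as a whole would also move mitochondrial genes with no copy listed on chromosome 1. The median absolute log2 fold change of mt-Nd1, mt-Nd2, mt-Nd5 and mt-Cytb was 0.0109. Counts of mt-Co2 and mt-Nd4l, which have listed copies, switched between the genotypes as well. Those of mt-Atp6 and mt-Co3, which also have listed copies, were 0 to 2 in every library of both genotypes. Read assignment that differed between libraries may explain it: of 36 genes on in some libraries and off in others, 29 switched within a genotype, and the 28 outside the mitochondrial set and its copies were more often overlapping genes, pseudogenes or ribosomal protein genes (odds ratio 3.75, Fisher's exact test p = 0.00145). That rests on leaving out genes that follow the meninges score: with this rule 9 of 9 settings of level and ratio had p under 0.05 (odds ratio 2.35 to 7.49), without it 2 of 9 (0.927 to 2.57), and why mt-Co1 and mt-Nd4 split by genotype stays open.

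The striatal list score was lower in all mutant libraries, with a camera adjusted p of 0.272 at an estimated correlation. Meningeal carry-over would remove the difference once its score was a covariate, but the median log2 fold change was then -0.646. Less striatal tissue in the mutant dissections may contribute: 6 GABAergic genes that striatal neurons share lay below 9 other interneuron genes by a mean log2 difference of -0.497. Those groups left out Dlx1, Dlx2 and Dlx6os1, and with these 3 among the shared genes the difference was -0.358, so the size depends on the choice of genes, and groups picked in view of their values decide nothing. Drd1 (0.01) and Six3 (-0.10) did not follow the other striatal markers, and an effect of the genotype or of sex stays open.

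Wild-type replicate 3 lacked both the Xist level of the mutants and Y-linked reads. In a female whose Xist reads were lost, genes that escape X inactivation would match the mutants, but 6 such genes lay lower by a mean log2 difference of -0.297 (SE 0.0999). In a male that lost Y-linked reads through a general loss, many other genes would be off. Of genes at 5 CPM or more in the other wild types, 0.00871% were off. A loss limited to Y-linked genes would leave other genes on, so this share cannot speak against it. A single X chromosome and no Y may explain it, as the 6 genes differed from the other wild types by 0.0611 (SE 0.0564). Those wild types had Y-linked reads, so this level cannot tell a single X from a male that lost only Y-linked reads. Each SE here is over genes, not over animals, and the mutants also differ in genotype. With all 11 X-linked genes that had been looked at, the differences were -0.301 (SE 0.129) to the mutants and -0.0465 (SE 0.108) to the other wild types, from 1 library. Single genes differed from the other wild types by -0.90 (Jpx) to 0.24 (Zfx).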
